A study of Oryza sativa Japonica Group with 9 samples.

How the data were processed

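RNA sequencing was applied to rice caryopses, the developing grains, of the japonica cultivar Nipponbare. There were 9 libraries in 3 groups of 3: wild type (WT), plants edited in GSK5 (a GSK3/SHAGGY-like protein kinase) and plants edited in ARF4 (an auxin response factor). Groups and replicate numbers came from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq kit. The sample labels give day 9 after flowering, whereas the series text gives days 7 to 8; which of these holds was not settled. Nothing in the labels says that the libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

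The deposited table gives FPKM (fragments scaled to the length of the gene model and to the mapped total of the library), rounded by the authors to 2 decimals, for 55986 rice gene models with MSU identifiers. Per the submitters' processing notes, Bowtie 0.12.2 and the build mm8 were used; mm8 is a mouse build, so it cannot describe rice gene models, and the rice build, annotation version and quantifier are not given in the sources used here. Reads were not used, and FPKM values are not counts, so no count model was fitted. Absolute depth is unknown. The steps of low values (0.1 to 0.5 FPKM) gave the relative depth of the libraries from 35 of the 36 pairs, the remaining pair being left out for its large residual. The residual was 0.008 log2, and the deepest library had 1.42 times the depth of the shallowest.

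Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested, which left 23385. Values were analysed as log2(FPKM + 1), so fold changes of genes with low FPKM are understated. One limma fit (limma 3.58.1 in R 4.3.3, with a mean-variance trend and without robust estimation) held a mean for each group and one shared spread, and gave GSK5 against WT, ARF4 against WT and GSK5 against ARF4. Adjusted p-values are Benjamini-Hochberg values over all genes tested within a comparison, and calls are adjusted p-values under 0.05 with no fold minimum. All adjusted p-values for genes come from this limma fit unless another fit is named. Tables were read and plots drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

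The fit was tested on simulated data with known changes, 8 simulations per noise model, each with 200 changed genes per edited group among 23385 genes. When every group was given the same spread, 4.6% of the calls in GSK5 against WT, 3.5% in ARF4 against WT and 4.7% in GSK5 against ARF4 fell on unchanged genes; in GSK5 against WT 37.8% of genes changed by 1 on the log2 scale and 78.9% of those changed by 2 were called, and in ARF4 against WT 37.2% and 80.4%. The measured groups do not have the same spread: the median SD within a group was 0.272 in WT, 0.114 in GSK5 and 0.241 in ARF4. With group spreads in that ratio, the share of calls on unchanged genes was 4.4% in GSK5 against WT, 18.9% in ARF4 against WT and 2.4% in GSK5 against ARF4. With each gene given its own SD in each group, which takes 3-library SDs at face value, it was 24.8%, 48.6% and 17.8%. The error rate set by the threshold is therefore not reached in every comparison, and least in ARF4 against WT, where the low spread of the GSK5 libraries lowers the shared estimate. For ARF4 against WT the fit over only the 2 groups compared gave 3.1% and 17.2% under the same 2 noise models. With group spreads as measured this fit called 7.5% of genes changed by 1 on the log2 scale, against 41.4% with all groups. Of genes changed by 2 it called 60.4%, against 80.8%. A call lost there is therefore weak evidence of no change where the change is near 1, and less weak where it is near 2. Under the same 2 noise models the fit over 2 groups gave 9.3% and 20.8% in GSK5 against WT and 7.2% and 19.5% in GSK5 against ARF4. The design was set before the data were examined and was kept, and the fit over 2 groups is given beside it.

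Gene lists were fixed before the data were examined, as 22 lists of which 21 have loci: Aux/IAA, SAUR and GH3, auxin synthesis and transport, auxin response factors, GSK3/SHAGGY-like kinases, brassinosteroid, grain size, starch synthesis, sucrose breakdown and sugar transport, seed storage proteins, endoplasmic reticulum folding, cell division cycle, cell wall loosening, cytokinin response, green pericarp photosynthesis, embryo, aleurone and lipid transfer, nucellus and maternal tissue, heat shock, circadian clock and defence. The heat shock, circadian clock and defence lists were set beforehand as checks of sampling and RNA state. The list of cytosolic ribosomal proteins, set for the same purpose, was defined by descriptions alone, which the table lacks, and was not tested. SAUR genes were likewise defined by descriptions alone, so the SAUR and GH3 list holds only GH3 genes and no SAUR gene was tested. Loci and symbols were written from memory. Of 228 loci, 225 are in the table used here. No identifier of the table matches one of the RefSeq gene table (assembly ASM3414082v1, used only for names and order), so each symbol was looked up there by its place along the chromosome within 1.5 Mb: 141 symbols were found at the matching place, 82 were not found and 5 were found elsewhere and dropped. Symbols not found are marked below as unchecked; the locus taken as GSK5 is one of them. A few symbols were looked up under a synonym. Lists were tested with limma's camera with a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, with Benjamini-Hochberg adjustment over the lists within a comparison. In 8 simulations of GSK5 against WT in which all 22 tested members of the starch list were raised by 1, camera ranked that list first 8 times. These simulations gave every group the same spread, drew genes independently and raised no other list. They therefore do not test camera on genes that move together, as those of the starch list do (estimated correlation 0.42).

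Genes were named by a rule fixed beforehand: the 2 edited genes, the largest changes among called genes whose libraries do not overlap between the groups, that reach a mean of 2 FPKM in the higher group and that have a checked name, and up to 3 called members per list. The rule admitted any gene with a name in the reference, but names were looked up only for list members. The largest changes with a name are therefore the largest among list members. Fewer shared rises and falls are given than the rule asked for. For lack of names, 2 identifiers that rose and 2 that fell were added per comparison, a choice made after the values were seen. The choice of uncalled list members given as values was also made then. These are the uncalled members of highest mean FPKM with a checked name, plus CHT3 among defence genes. Shared calls were set beside the product of the list sizes over the genes tested and beside 100 simulations of unchanged groups. In these all 9 libraries, WT included, were redrawn with each gene independent of the others. Both simulated edited groups were compared with the same simulated WT group. The 3 control libraries cannot be split. Alternatives covered the pseudocount, the filter on low values, the scaling, the test settings, the libraries in the fit, a replicate block, each library left out in turn and a fold minimum. Array quality weights were estimated gene by gene, chosen after limma's default method did not converge. The fit without WT replicate 1 and ARF4 replicate 2, and list tests with checked names alone, were added after the data were seen.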

Results

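Transcript levels were measured by RNA sequencing in caryopses of WT, GSK5-edited and ARF4-edited rice, 3 libraries per group. Summed FPKM per library lay between 585414 and 626390, and 20840 to 23172 genes per library reached 1 FPKM. Relative depth was 100%, 98% and 95% in WT replicates 1, 2 and 3, 84%, 88% and 71% in the GSK5 replicates and 94%, 84% and 80% in the ARF4 replicates, with the deepest library set to 100%. The GSK5 libraries resembled each other most: the mean Pearson r of a library with its own group across genes, which are not independent replicates, was 0.97 to 0.981 in GSK5, 0.91 to 0.939 in WT and 0.898 to 0.939 in ARF4. WT replicate 3 had r of 0.945, 0.946 and 0.931 with the GSK5 replicates, above its mean of 0.91 with its own group. ARF4 replicate 3 had r of 0.918, 0.932 and 0.941 with the GSK5 replicates, above its own-group mean of 0.901. By mean r these 2 libraries therefore lay closer to the GSK5 group than to their own, but single pairs differed. ARF4 replicate 3 had r of 0.943 with ARF4 replicate 1, its highest, and 0.86 with ARF4 replicate 2. WT replicate 3 had r of 0.935 with WT replicate 2 and 0.884 with WT replicate 1. The first principal component held 36.2% of the variance, with WT replicate 1 and ARF4 replicate 2 at its ends.

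The edited genes themselves were examined first, since they bear on the labels. The locus taken as GSK5 (LOC_Os03g62500, name unchecked) had 32.21 ± 1.56 FPKM in GSK5-edited caryopses and 39.79 ± 7.95 in WT (SD, n = 3), a log2 change of -0.28 with SE 0.17 that did not pass the limma test (adjusted p = 0.395). ARF4 (LOC_Os01g70270) fell in ARF4-edited caryopses, from 83.96 ± 14.2 to 50.45 ± 3.4 FPKM, with a log2 change of -0.71, SE 0.14 and adjusted p = 0.0388. Each ARF4-edited library lay under each WT library. In GSK5-edited caryopses ARF4 stood at 78.29 ± 5.58 FPKM (adjusted p = 0.744). The ARF4 call was lost in the fit over only the 2 groups compared (adjusted p = 0.172) and without any one of WT replicates 1 and 2, ARF4 replicates 1 and 3 or a GSK5 library, with adjusted p between 0.0626 and 0.135. It was also lost with no filter on low values (0.0542), median-of-ratios scaling (0.0573) and the replicate number as a block (0.0958). The log2 change stayed between -0.64 and -0.86. An edit can leave the transcript level unaltered, so a level near that of WT does not speak against a label.

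**Figure D1:**
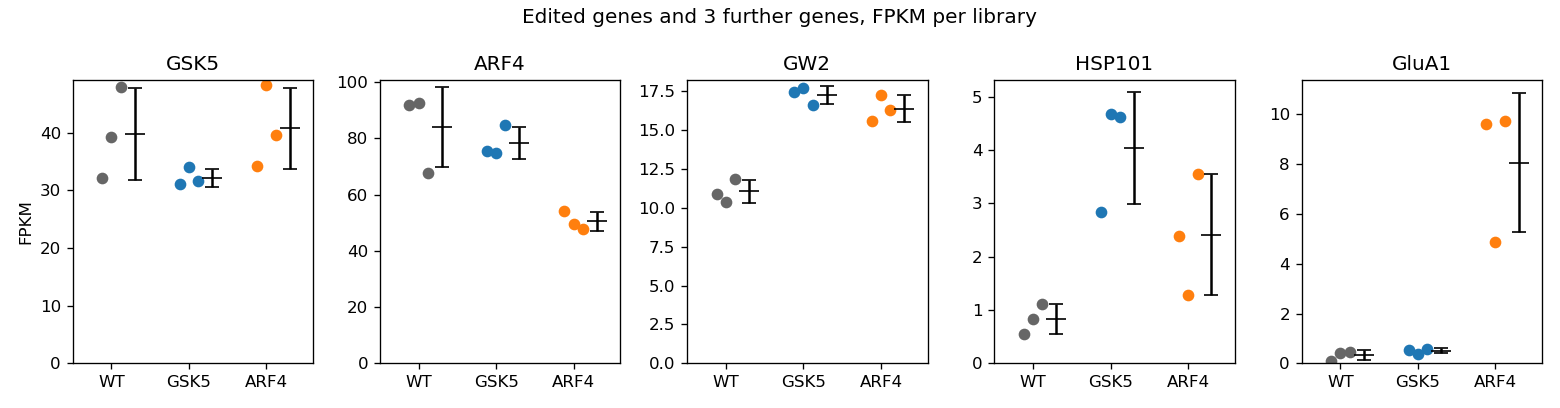
FPKM (vertical axes, from 0) in each of the 9 libraries (points) of WT, GSK5-edited and ARF4-edited caryopses, with the group mean and SD as bars, for GSK5, ARF4, GW2, HSP101 and GluA1. GW2 averaged 11.04 FPKM in WT against 17.25 and 16.36 in the edited groups, and GluA1 averaged 8.067 FPKM in the ARF4 libraries against 0.3267 in WT.

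What distinguishes GSK5-edited from WT grain was the first comparison. Heat shock genes, most of which encode chaperones, were higher as a list by camera with the preset correlation (adjusted p = 4e-04). They did not pass with an estimated correlation (adjusted p = 0.881) or with the 4 checked names alone (adjusted p = 0.208). Fry gave adjusted p = 0.0383. Heat shock genes were set as a check of sampling and RNA state, so their rise cannot be assigned to the edit. Of 8 tested members 3 rose and 5 were not called, and 6 rose when adjusted over the list alone; the median log2 change was 1.49. HSP101, a disaggregating chaperone, rose from 0.8367 ± 0.285 to 4.04 ± 1.05 FPKM, by 1.45 on the log2 scale (SE 0.28, adjusted p = 0.044). Members entered as HSP82A and HSP18 (LOC_Os04g01740 and LOC_Os03g16030, names unchecked) rose by 2.74 (SE 0.4) and 2.43 (SE 0.35), to 22.3 ± 9.9 and 12.43 ± 4.51 FPKM. HSP101 lost its call without any one of WT replicates 1 and 2, the 3 GSK5 libraries or ARF4 replicate 1 (adjusted p up to 0.201), with log2(FPKM + 5) (0.0538), with no filter (0.0704) and under median-of-ratios scaling (0.0654) or quantile normalization (0.106). The replicate number as a block also ended that call (0.0732). HSP82A lost it without WT replicate 1 or 2 or GSK5 replicate 2 or 3 (up to 0.0811), and HSP18 without WT replicate 2 or GSK5 replicate 2 or 3 (up to 0.0744).

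Genes of the photosynthetic apparatus, a marker of the green pericarp, were lower as a list in GSK5-edited grain. Of 17 tested members 1 fell and 16 were not called, also when adjusted over the list alone, with a median log2 change of -0.23. Camera gave adjusted p = 0.0109, and adjusted p = 0.881 with an estimated correlation or 0.231 with the 3 checked names alone. Fry gave adjusted p = 0.546. The called member was RCA, the activase of Rubisco, at 108.8 ± 19.7 FPKM against 198 ± 19 in WT (log2 change -0.87, SE 0.17, adjusted p = 0.0399). Without WT replicate 1 or GSK5 replicate 3 the list was no longer past the threshold (adjusted p = 0.0726 and 0.0884), nor under quantile normalization (0.233). RCA lost its call without any one of WT replicates 1 and 2, the GSK5 libraries or ARF4 replicate 1 (adjusted p up to 0.182), with either other filter (0.0547 and 0.0523), under quantile normalization (0.0632) and in the fit over only the 2 groups (0.0629).

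Of 22 tested starch synthesis genes 1 rose and 21 were not called, with 2 risen when adjusted over the list alone and a median log2 change of 0.5. The mean log2 level of this list was 3.46, 3.77 and 4.64 in WT replicates 1, 2 and 3 and 4.39 to 4.58 in GSK5, so WT replicate 3 lay above every GSK5 library. The member entered as AGPL2 (LOC_Os01g44220, name unchecked), listed as a large subunit of ADP-glucose pyrophosphorylase, rose from 24.81 ± 1.99 to 81.18 ± 13.2 FPKM (log2 change 1.66, SE 0.15, adjusted p = 0.00169). That call held in all 21 alternatives run for it, with adjusted p up to 0.0123. SSI, a soluble starch synthase, stood at 66.1 FPKM against 57.81 in WT (adjusted p = 0.621). Of 14 grain size genes 1 rose and 13 were not called, also when adjusted over the list alone, with a median of 0.21. That gene was GW2, a RING-type ubiquitin ligase that restrains grain width, at 17.25 ± 0.584 FPKM against 11.04 ± 0.748 in WT (log2 change 0.6, SE 0.1, adjusted p = 0.0224). Its call was lost without any one of WT replicates 1 and 2 or a GSK5 library (adjusted p up to 0.129), and with the replicate number as a block (0.0862). Of 7 cytokinin response genes 1 rose and 6 were not called; adjusted over the list alone 1 rose and 3 fell, and the median was -0.36. The riser was the member entered as RR3 (LOC_Os02g58350, name unchecked), at 19.06 ± 0.775 FPKM against 10.55 ± 1.1 (log2 change 0.8, adjusted p = 0.0105), which lost its call without WT replicate 2 or any GSK5 library (adjusted p up to 0.0727).

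No tested member of the other lists was called in GSK5 against WT by limma, over all genes or adjusted over the list alone, and neither these lists nor those of starch, grain size and cytokinin passed camera. Among 24 Aux/IAA genes, repressors of auxin signalling, the most abundant were IAA17 at 223.3 FPKM against 142.8 in WT (adjusted p = 0.388) and IAA21 at 152.3 against 110.1 (0.403). The 10 auxin response factors had a median log2 change of 0.36, the 4 auxin synthesis and transport genes 0.8, the 5 GH3 genes -0.43 (mean 0.06) and the 4 GSK3/SHAGGY-like kinases 0.01. The 9 brassinosteroid genes had a median of 0.28, with the receptor kinase gene BAK1 at 31.04 FPKM against 26.9 (adjusted p = 0.588). The 10 cell wall loosening genes had a median of 1.3, with EXPB3 at 1294 FPKM against 824.7 (adjusted p = 0.394); their mean log2 level ran from 3.2 to 6.76 among the WT libraries. The 9 sugar genes had a median of 0.3, with a negative sign in camera and no difference shown from other genes (adjusted p = 0.864), and the sugar transporter gene SWEET11 stood at 1375 FPKM against 793.3 (adjusted p = 0.47). Medians were 0.29 for 5 endoplasmic reticulum folding genes, -0.15 for 4 cell division genes, 0.11 for 2 storage protein genes, 0.16 for 9 clock genes and -0.62 for 6 defence genes. The remaining tissue markers had medians of -0.03 (6 embryo genes, mean 0.11), 0.46 (3 aleurone and lipid transfer genes) and -0.41 (3 nucellus and maternal genes). Without WT replicate 3 camera called cell wall loosening and starch genes higher (adjusted p = 0.000849 for each), auxin synthesis and transport genes higher (0.0384) and defence genes lower (0.00334). Under quantile normalization it called cell wall loosening and starch genes higher (0.0451 for each). These calls use the preset correlation; with an estimated correlation, run with all libraries and the reported scaling only, each of these 4 lists had adjusted p = 0.881.

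In all, limma called 502 of 23385 genes in GSK5 against WT, 338 higher and 164 lower, and 4320 had an unadjusted p under 0.05. With quantile normalization 234 were higher and 182 lower. The table does not pair identifiers with names. LOC_Os03g02470 rose from 0.15 ± 0.0361 to 338.5 ± 18.6 FPKM and LOC_Os07g26100 from 0.02667 ± 0.00577 to 187 ± 46.3, whereas LOC_Os10g22630 fell from 656.4 ± 265 to 0.7367 ± 0.223 and LOC_Os01g27140 from 51.63 ± 22.2 to 0.73 ± 0.437; these 4 calls held in all 21 alternatives run for each. The alternatives do not test whether the genome of the WT plants differs from that of both edited lines. Such a difference stays open for LOC_Os03g02470 and LOC_Os07g26100, as weighed below. The groups did not overlap for 30.1% of genes, where libraries drawn with the same mean and spread would give 10% on average. The spreads of the groups differ and genes move together, so 10% is only a rough guide in each comparison. The count was 204, 170 and 2719 without WT replicate 1, 2 or 3, 151, 135 and 137 without GSK5 replicate 1, 2 or 3 and 333 without ARF4 replicate 1, and the fit over only the 2 groups compared called 564. In simulated data with group spreads as measured 4.4% of calls fell on unchanged genes, and 24.8% when each gene had its own SD in each group.

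**Figure D2:**
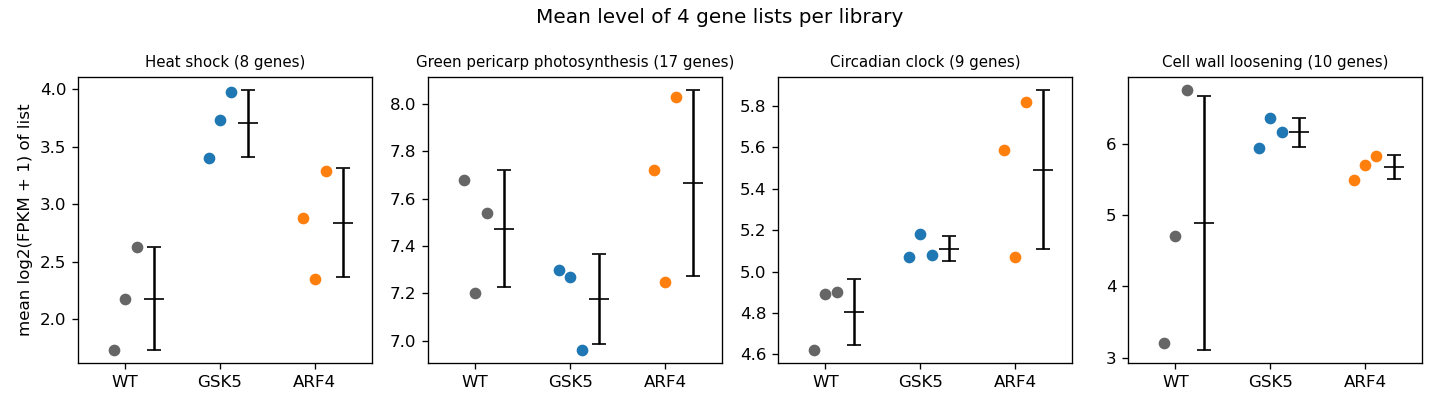
Mean log2(FPKM + 1) of the tested members of 4 gene lists (vertical axes, not from 0) in each of the 9 libraries (points), with the group mean and SD as bars. The GSK5 libraries lie at 3.4 to 3.98 for heat shock genes against 1.73 to 2.63 in WT, and cell wall loosening genes range from 3.2 to 6.76 among the WT libraries.

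ARF4-edited grain was compared with WT next. Clock genes included 2 that rose among 9 tested, with 7 not called; adjusted over the list alone 4 rose and 1 fell. PRR95, a pseudo-response regulator, rose from 7.04 ± 4.78 to 54.89 ± 26.6 FPKM (log2 change 2.85, SE 0.49, adjusted p = 0.0247), and LHY, a MYB-type clock gene, from 6.883 ± 0.61 to 29.63 ± 14.1 (log2 change 1.83, SE 0.36, adjusted p = 0.0363). ARF4 replicate 2 stood below replicates 1 and 3, at 28.02 FPKM against 55.43 and 81.21 for PRR95 and 14.26 against 32.62 and 42 for LHY. The mean log2 level of the clock list was 5.07 in that library, 5.59 and 5.82 in ARF4 replicates 1 and 3 and 5.07 to 5.18 in GSK5. As a list the clock genes did not pass camera (adjusted p = 0.211). They too were set as a check of sampling, so the rises of PRR95 and LHY cannot be assigned to the edit. Of 2 tested storage protein genes 1 rose, GluA1, which encodes a glutelin, from 0.3267 ± 0.189 to 8.067 ± 2.78 FPKM (log2 change 2.73, SE 0.26, adjusted p = 0.00184); this call held in all 20 alternatives run for it. Glutelin genes are a family of close copies, so the value of any one is uncertain. The list of 2 gave adjusted p = 0.122 with camera, 0.796 with an estimated correlation, and adjusted p = 0.00104 with fry.

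Among hormone genes, 1 of 9 brassinosteroid genes rose and 8 were not called, with 3 risen and 1 fallen when adjusted over the list alone. The riser was BZR1, a transcription factor of brassinosteroid signalling and a known substrate of GSK3-like kinases, at 35.92 ± 6.72 FPKM against 16.06 ± 4.79 in WT (log2 change 1.14, SE 0.23, adjusted p = 0.0382). Of 24 Aux/IAA genes 1 fell and 23 were not called, with 1 risen and 1 fallen when adjusted over the list alone; IAA25 fell from 16.84 ± 3.45 to 8.093 ± 1.35 FPKM (log2 change -0.96, SE 0.17, adjusted p = 0.0289). Of 10 auxin response factors only ARF4 itself was called, also when adjusted over the list alone. The log2 change was above 0 for 9 of the 10, with a median of 0.52. For Aux/IAA genes it was above 0 for 15 of 24, with a median of 0.45. Neither list passed camera (adjusted p = 0.211 and 0.581). The unchecked RR3 rose to 18.32 ± 1.13 FPKM (log2 change 0.75, adjusted p = 0.014), the single call among 7 cytokinin response genes; adjusted over the list alone 1 rose and 1 fell. GW2 rose to 16.36 ± 0.856 FPKM (log2 change 0.53, SE 0.1, adjusted p = 0.0309), the single call among 14 grain size genes, of which 3 rose when adjusted over the list alone. Among 17 photosynthesis genes RBCS2, a Rubisco small subunit gene with close copies, fell from 111.5 ± 48.5 to 28.85 ± 8.04 FPKM (log2 change -1.84, SE 0.37, adjusted p = 0.0385), and 16 were not called; adjusted over the list alone 2 rose and 2 fell. CAB2R stood at 1026 FPKM against 596.2 (adjusted p = 0.246).

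The calls for PRR95, LHY, BZR1, IAA25, GW2, RBCS2 and RR3 were lost in the fit over only the 2 groups compared, with adjusted p of 0.129, 0.142, 0.16, 0.143, 0.18, 0.158 and 0.117. They were also lost when single libraries were left out. Without ARF4 replicate 1 the adjusted p was 0.107 for PRR95, 0.152 for LHY, 0.0884 for BZR1, 0.124 for IAA25, 0.111 for GW2, 0.151 for RBCS2 and 0.0549 for RR3. Without WT replicate 1 it was 0.0567 for PRR95, 0.0899 for LHY, 0.064 for BZR1, 0.0678 for IAA25, 0.0671 for GW2 and 0.0966 for RBCS2. Without WT replicate 2 it was 0.0913 for PRR95, 0.111 for LHY, 0.11 for BZR1, 0.108 for IAA25, 0.118 for GW2 and 0.0639 for RR3. Without GSK5 replicate 2 it was 0.0553 for PRR95, 0.0652 for LHY, 0.0802 for BZR1, 0.0652 for IAA25, 0.0747 for GW2 and 0.0778 for RBCS2, and these 6 were lost likewise without GSK5 replicate 1 or 3. With no filter LHY, BZR1 and RBCS2 were lost (0.0598, 0.0591 and 0.063), and LHY with median-of-ratios scaling or quantile normalization (0.051 and 0.0554). The replicate number as a block was another setting in which LHY was lost (0.0986). BZR1 was lost, too, without ARF4 replicate 2 or 3 (0.0508 and 0.0573).

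No tested member of the other lists was called by limma in ARF4 against WT, and none of the 21 lists passed camera. Among 6 defence genes, with 3 fallen when adjusted over the list alone, the median log2 change was -1.29, and the most abundant member, PBZ1, stood at 164.9 FPKM against 249 in WT with a log2 change of 0.11 (adjusted p = 0.942). The chitinase gene CHT3, the member of largest change, stood at 8.56 FPKM against 72.44, 121.51 and 19.21 in WT replicates 1, 2 and 3 (adjusted p = 0.103), and the mean log2 level of the list was 5.37, 6.74 and 3.75 in these replicates. The 8 heat shock genes had a median of 0.77, with 1 risen when adjusted over the list alone. The 10 cell wall loosening genes had a median of 0.51, with EXPB3 at a log2 change of 0.27 (adjusted p = 0.868), although its mean was 608.3 FPKM against 824.7 in WT, where the replicates stood at 111.27, 489.61 and 1873.13. The 22 starch genes had a median of 0.11, the 9 sugar genes -0.17, the 5 endoplasmic reticulum folding genes 0.54 and the 4 cell division genes 0.23. Medians were 0.42 for the 4 auxin synthesis and transport genes and -0.01 for the 4 GSK3/SHAGGY-like kinases. The 5 GH3 genes had a median of 0.07 (mean -0.13, with 1 fallen when adjusted over the list alone). Tissue markers had medians of -0.28 (6 embryo genes, 1 of which fell when adjusted over the list alone), 0.09 (3 aleurone and lipid transfer genes) and -0.08 (3 nucellus and maternal genes). Without WT replicate 3 camera called cell wall loosening genes higher (adjusted p = 0.00615) and defence genes lower (0.00411), and without ARF4 replicate 2 clock genes higher (0.0255). With no filter it called defence genes lower (0.028) and storage protein genes higher (4.55e-09). These calls use the preset correlation; with an estimated correlation, run with all libraries and the reported filter only, each of these 4 lists had adjusted p = 0.796.

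In all, limma called 776 genes in ARF4 against WT, 304 higher and 472 lower, with 5825 at an unadjusted p under 0.05, but only 82 genes, 64 higher and 18 lower, when the 2 groups compared set the spread alone. In simulated data with group spreads as measured, 18.9% of the calls of the fit over all groups fell on unchanged genes, and 48.6% when each gene had its own SD in each group, so the larger count is not held to the 0.05 rate. By identifier, LOC_Os03g02470 rose to 463.1 ± 132 FPKM and LOC_Os07g26100 to 221.4 ± 62.5, in all 21 alternatives run for each, whereas LOC_Os01g62970 fell from 112.2 ± 88.5 to 5.15 ± 1.77 and LOC_Os05g15880 from 73.36 ± 23.9 to 5.33 ± 3.49; in the fit over 2 groups the last 2 had adjusted p of 0.0806 and 0.0518. LOC_Os01g62970 was also lost without WT replicate 2 or ARF4 replicate 1 (0.0615 and 0.0742). For LOC_Os03g02470 and LOC_Os07g26100 a genome difference between the WT plants and both edited lines stays open here too. The groups did not overlap for 23.7% of genes, where libraries drawn with the same mean and spread would give 10% on average. The count was 330, 178 and 3498 without WT replicate 1, 2 or 3, 156, 1907 and 1287 without ARF4 replicate 1, 2 or 3, and 292, 294 and 302 without GSK5 replicate 1, 2 or 3. Without both WT replicate 1 and ARF4 replicate 2, a choice made after the data were seen, it was 1999, and 515 in GSK5 against WT. The split into higher and lower calls turned to 106 and 72 without WT replicate 2. It was 94 and 62, 984 and 923, and 803 and 484 without ARF4 replicates 1, 2 and 3. Lower calls still outnumbered higher ones without any other single library.

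The edited genotypes were then set against each other directly. Glutelin gene GluA1 was lower in GSK5 than in ARF4 (log2 change -2.54, SE 0.26, adjusted p = 0.00957), and the unchecked AGPL2 and HSP82A were higher in GSK5, by 1.48 (adjusted p = 0.0102) and 3.16 (adjusted p = 0.0231). GluA1 and HSP82A lost their calls without GSK5 replicate 2 or 3 or ARF4 replicate 1 (adjusted p up to 0.0562 and 0.119), and AGPL2 kept its call in all 21 alternatives run for it (up to 0.0488). Photosynthesis genes were lower in GSK5 as a list by camera (median log2 change -0.66, adjusted p = 0.00018). None of 17 was called over all genes, and 1 rose and 3 fell when adjusted over the list alone. With an estimated correlation adjusted p = 0.867. With the 3 checked names alone, too few to stand for the list, the mean log2 difference was 0.02. Of these, RBCS2 stood at 87.84 FPKM in GSK5 against 28.85 in ARF4, and RCA at 108.8 against 185.9. The 2 storage protein genes gave adjusted p = 0.00739, and adjusted p = 0.302 with an estimated correlation. Fry gave adjusted p = 0.00162 for the storage list and 0.518 for the photosynthesis list. For GW2 the difference was 0.07 (adjusted p = 0.798) and for RR3 0.06 (adjusted p = 0.866). The clock genes PRR95 and LHY differed by -1.55 and -1.34 between GSK5 and ARF4, short of the threshold (adjusted p = 0.227 and 0.175), so they are not shown to change in ARF4 alone. Camera gave adjusted p = 0.0524 for heat shock genes (median 0.73), 0.0608 for clock genes (-0.38) and for cell division genes (-0.55), and 0.0684 for starch genes (0.41); with an estimated correlation adjusted p was 0.867 for the first 3 of these lists and 0.889 for starch. Heat shock genes passed with log2(FPKM + 5) (0.0304), median-of-ratios scaling (0.024) and quantile normalization (0.0259), starch genes with the same 2 scalings (0.0419 and 0.0448) and cell division genes with no filter (0.000167). Each of the 4 lists also passed when some single libraries were left out, with 0.00625 for heat shock without GSK5 replicate 1, 0.0409 without GSK5 replicate 2, 0.0293 without ARF4 replicate 1 and 0.014 without ARF4 replicate 3. Clock genes passed without GSK5 replicate 2 (0.0409) or ARF4 replicate 2 (0.000669) and cell division genes without ARF4 replicate 1 (0.0293) or 3 (0.014). Starch genes passed without WT replicate 3 (0.0238), GSK5 replicate 3 (0.0402) or ARF4 replicate 3 (0.0471). Grain size genes had a median of 0.11 and a mean of -0.06, and GSK3/SHAGGY-like kinases a median of 0.08; camera's sign was negative for both, but neither was shown to differ from other genes (adjusted p = 0.816 and 0.936).

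Limma called 113 genes in GSK5 against ARF4, 72 higher and 41 lower in GSK5, with 3236 at an unadjusted p under 0.05. The groups did not overlap for 26.3% of genes, where libraries drawn with the same mean and spread would give 10% on average. LOC_Os06g46740 was higher in GSK5, at 41.64 ± 4.85 FPKM against 2.03 ± 2.41, as was LOC_Os07g02690, at 19.36 ± 12.7 against 0.55 ± 0.164. LOC_Os10g22630 was lower in GSK5, at 0.7367 ± 0.223 FPKM against 287.3 ± 64.8, as was LOC_Os01g04000, at 0.07333 ± 0.0643 against 89.57 ± 22.5. LOC_Os06g46740 lost its call without any one of the GSK5 libraries or ARF4 replicate 1 (adjusted p up to 0.114) and LOC_Os07g02690 without GSK5 replicate 3 or ARF4 replicate 1 (up to 0.0544). The split into higher and lower calls moved with the scaling, to 44 and 43 with median-of-ratios factors, 47 and 47 with quantile normalization and 52 and 46 without the 100 highest genes. It turned when single libraries were left out, to 8 higher and 13 lower without ARF4 replicate 1, 180 and 244 without ARF4 replicate 2, 172 and 332 without ARF4 replicate 3 and 8 and 9 without GSK5 replicate 3. The count was 173 and 66 without WT replicate 1 or 2, 36, 25 and 17 without GSK5 replicate 1, 2 or 3, and 21, 424 and 504 without ARF4 replicate 1, 2 or 3, and the fit over only the 2 groups compared called 205.

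Whether the same genes moved in the edited genotypes was asked last. Relative to WT, 120 genes rose in both and 107 fell in both, and 0 were called in opposite directions. GW2 and the unchecked RR3 rose in both. LOC_Os03g02470 and LOC_Os07g26100 had the largest shared rises, and LOC_Os05g15880 and LOC_Os04g27670 the largest shared falls, the second from 85.43 ± 43 FPKM to 2.737 ± 2.21 in GSK5 and 6.9 ± 3.78 in ARF4; it lost its call in GSK5 without WT replicate 1 or 2 or GSK5 replicate 1 or 2 (adjusted p up to 0.059) and in ARF4 without WT replicate 1 or 2, GSK5 replicate 1 or ARF4 replicate 1 (up to 0.11), with no filter (0.0524) and with only the 2 groups compared (0.0979). Independent lists of these sizes would share 4.4 risen and 3.3 fallen genes. Simulated unchanged groups against the same simulated WT group shared a mean of 1.06 and 1.45, at most 4 and 8. For opposite directions the values were 9 and 0. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.608, below the 0.635 of unchanged groups, so the correlation alone shows no shared effect. Their covariance was 0.234 against a simulated 0.089, a difference of 0.144. The simulation drew each gene independently, so it leaves out WT libraries that shift many genes together. It therefore cannot show how many shared calls or how much covariance such a shift would give. Part of the excess of shared calls may come from the shared WT libraries, which cannot be split. LOC_Os03g02470 and LOC_Os07g26100 are among 17 genes under 0.5 FPKM in all WT libraries and at 5 or more in all edited ones. For these 17 genes, weighed below, stretches of the genome that differ between the WT plants and both edited lines stay open as a cause. Their shared rises therefore cannot be assigned to the edits. The split into rises and falls did not hold: 51 rose and 10 fell in both in the fits over 2 groups, 68 and 17 without WT replicate 2, 74 and 38 without WT replicate 1, 69 and 23, 66 and 21, and 67 and 20 without GSK5 replicates 1, 2 and 3, 66 and 22 without ARF4 replicate 1, 291 and 140 without ARF4 replicate 2, and 780 and 848 without WT replicate 3. The shared calls numbered 227, but 61 in the fits over 2 groups, 112, 85 and 1628 without WT replicate 1, 2 or 3, 92, 87 and 87 without GSK5 replicate 1, 2 or 3, and 88 and 431 without ARF4 replicate 1 or 2.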

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

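The tests of scaling, depth, large shares, shared reads and endosperm content were chosen after the result was seen, while those of clustering along the chromosome, of the ranges of tissue lists and of regrouped libraries were set before. The results given first stand out because the change relative to WT differed between the edited genotypes by the limma test of GSK5 against ARF4, or by camera for lists; groups of 3 are too small for a test of outlying samples. The log2 change in GSK5 minus that in ARF4 was -7.36 for LOC_Os10g22630, -6.37 for LOC_Os01g04000, 4.09 for LOC_Os06g46740, 3.55 for LOC_Os07g02690, 3.16 for HSP82A, 1.48 for AGPL2 and -2.54 for GluA1. The mean difference over the photosynthesis list was -0.49 and over the storage protein list -1.39. Neither list passed camera with an estimated correlation (adjusted p = 0.867 and 0.302). The photosynthesis difference was 0.02 with checked names alone, which are 3 of the 17 tested members. Regrouping the 6 libraries of a comparison makes 10 splits, too few for a share under 0.05: the 1 real split called 502 genes in GSK5 against WT and the highest other 81, 776 and 3 in ARF4 against WT, and 113 and 0 in GSK5 against ARF4.

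A first pattern is that 17 genes stood under 0.5 FPKM in all WT libraries and at 5 FPKM or more in all 6 edited libraries, with 0 genes the other way round, while 3 such genes were on in GSK5 alone and 6 in ARF4 alone. The median absolute log2 change of these genes in GSK5 against WT was 4 after median-of-ratios scaling. The choice of these genes fixed a large change beforehand, so this test cannot decide on a difference of scaling. A scaling difference alone would shift all genes of a library alike. The median log2 change over all genes tested was 0.114 in GSK5 against WT and 0.053 in ARF4 against WT. Stretches of the genome that differ between the WT plants and both edited lines could put such genes side by side; 0% of them had another within 10 loci, but 93.7% of 10000 random sets of 17 also had none, so the bound set beforehand was too loose to argue against it and this cannot be told apart from scattered changes. The labels give one cultivar for all plants, and a shared effect of both edits stays open as well.

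A second pattern is the unequal spread within groups, with a median SD in WT 2.39 times that in GSK5. Depth is argued against, since the ratio was 2.98 among genes of at least 20 FPKM and the WT libraries are the deeper ones, and so are a few genes with large shares, since it was 2.43 after median-of-ratios scaling. Grains of different stage or tissue make-up among libraries of one group may contribute: the median range of 4 tissue lists was 1.87 times as wide in WT as in GSK5, at 0.44 and 0.23, and 0.75 in ARF4. The ranges do not follow the spread throughout, since that of ARF4 exceeds that of WT although its median SD is lower (0.241 against 0.272), the embryo list ranged less in WT (0.4) than in GSK5 (0.79) and the nucellus list less in ARF4 (0.07) than in GSK5 (0.13). A wider spread of another origin would also widen such ranges, so this stays a hypothesis.

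Another pattern is that, in libraries labelled caryopsis, 7 of 9 seed storage protein genes averaged under 1 FPKM, and Wx, which encodes the granule-bound starch synthase of endosperm, averaged 1.22 FPKM; GluA1 was an exception in ARF4, with a mean of 8.067 FPKM. Reads shared between near-identical copies stay open as a cause for the storage genes, because the level of Wx belongs to the pattern itself and cannot serve as a test. Little starchy endosperm in the tissue, or an earlier stage than labelled, could also give this. The photosynthesis list had 1006 times the median FPKM of the storage list, which restates the low storage level and supports neither, and tissue and stage cannot be told apart here because all libraries carry the same labels.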

How the results depend on the processing

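The planned count-based tool was not run, since FPKM values are not counts. The removal of WT replicate 1 together with ARF4 replicate 2, the use of checked names alone and the method for array weights were chosen after seeing the data. Counts within 1.5 times of the reported ones are not listed, and the cause was not tested unless stated. In GSK5 against WT 502 calls became 212 with at least 5 FPKM (fewer genes tested), 9191 with array weights and 135 to 2719 with single libraries left out. In ARF4 against WT 776 became 82 with only the 2 groups compared, 503 with a fold minimum, 11638 with array weights, 1999 without WT replicate 1 and ARF4 replicate 2, and 156 to 3498 with single libraries left out. In GSK5 against ARF4 113 became 69 with log2(FPKM + 0.1), 220 with no filter, 65 with at least 5 FPKM, 8908 with array weights, 205 with only the 2 groups, 906 without WT replicate 1 and ARF4 replicate 2, and 17 to 504 with single libraries left out. The 227 shared calls became 120 with at least 5 FPKM, 5811 with array weights, 61 with only the 2 groups, 355 without WT replicate 1 and ARF4 replicate 2, and 85 to 1628 with single libraries left out. The correlation ran from 0.524 to 0.726 with single libraries left out.

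Array weights ran from 0.236 to 5.43 and were estimated from the same 9 libraries; the weighted fit also called up to 7534 genes in a regrouped split of GSK5 against WT, so its counts are not read as effects. With the replicate number as a replicate block the counts were 239, 219 and 30, with 98 shared calls. Deviations of same-number libraries from their group means had r from -0.35 (WT and GSK5 replicates 3) to 0.08 (GSK5 and ARF4 replicates 2). Libraries of different number had r from -0.32 to 0.35. No sign of pairing by number was therefore seen. Deviations centred within groups of 3 cannot show that the samples are unpaired. Quantile normalization moved the higher calls of GSK5 against WT from 67.3% to 56.2%, to 234 higher and 182 lower, and the median change of all genes from 0.114 to -0.006, a shift to which changes in that comparison are relative. Of 774 values for 37 named results, 637 kept direction and side of the threshold, 132 lost the call, 1 gained it and 4 changed sign. The gain was the GSK5 gene in GSK5 against WT, at -0.27 in the limma fit with array weights (adjusted p = 0.0466). The sign changed for GSK5 in ARF4 plants, uncalled at 0.04. It was -0.01 with median-of-ratios scaling, -0.16 with array weights, -0.1 without WT replicate 1 and -0.09 without ARF4 replicate 2, and reached 0.18 without WT replicate 3. Of 75 values for 4 list results, 65 kept both and 9 lost the call. The photosynthesis list in GSK5 against ARF4 turned to 0.02 with checked names alone, which are 3 of its 17 tested members. Absolute depth is unknown, so no limit of detection is given.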

Other observations

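Cell division genes were mostly too low to test: 4 of the 12 members passed the filter. The untested CYCB1-1, a mitotic cyclin, stood at 2.82, 8.58 and 0.09 FPKM in ARF4 replicates 1, 2 and 3, and at 0.07 to 0.88 in the WT and GSK5 libraries. MCM5, a replication licensing factor, stood at 1.63, 6.42 and 0.11 FPKM in the ARF4 replicates and at 0.02 to 0.63 in the others, so the higher values came from ARF4 replicates 1 and 2 and not from the whole group. The untested glutelin gene GluB2 stood at 0.22, 0.41 and 0.44 FPKM in the ARF4 replicates and at 0 to 0.08 in the others; the members of this gene family are close copies. These genes were not tested, and were chosen after their values were seen.

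The expansin genes EXPB3 and EXPB4 averaged 909.1 and 265.3 FPKM over all libraries, in a cell wall loosening list with a median of 38.03 and a lowest member at 0.2156. MADS7, entered in the nucellus and maternal tissue list, stood at 296.7, a level that does not by itself measure nucellus content. The lipid transfer genes entered as LTP1 and LTP3 (names unchecked) stood at 1105 and 1432 FPKM.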
